A study of Mus musculus with 6 samples.

How the data were processed

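RNA was measured in ILC2s sorted from the lungs of mice given PBS or papain, with 3 libraries per treatment. Per the labels' protocols, total RNA was extracted with Trizol, full-length cDNA was made with the SMART-Seq HT kit and libraries were made with a transposase kit, which does not mark strand. The dose, the schedule and the gates of the sort were not given in the sources used here. The submitters' processing notes name HISAT2, Cufflinks and mm10, and the tool and annotation that made the gene table were not given in the sources used here.

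The deposited count table held whole read counts per gene in every library, with 28912 genes, of which 28738 had a gene symbol and 174 had none. Both tables had a column for each of the 6 samples and 0 columns for others. Gene IDs were matched to GENCODE mouse release M21 on GRCm38 (mm10) for positions, overlaps and GC content. Gene lengths were those implied by the counts and the authors' FPKM table. Total counts were 6552173 to 8082556 per library, and no molecular identifiers were used, so intervals and floors cover counting error only. The authors' FPKM table, which the deposited labels call FPKM, did not hold plain FPKM in every place. For 8619 genes (29.8%, holding 2.51% of counts) its values were below 0, in the proportion given by a length of -1, and these genes were left out of it. For the other 20293 genes each value equalled the count per length and total times a factor between 0.924 and 1.082, which changed with the position of the gene in the table in 6 repeating patterns. FPKM was therefore also recomputed with 1 factor per library.

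Choices of test, gene lists, rule for named genes and alternatives were made before the data were examined, except those said to have been added. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filterByExpr filter on treatment, robust quasi-likelihood fits and Benjamini-Hochberg adjustment over the 12918 genes kept. The threshold was an adjusted p of 0.05. The biological coefficient of variation was 0.246 and the prior degrees of freedom of the robust fit had a median of 7.13. The test had 3 samples against 3 and no covariate. Levels are CPM, that is, counts scaled to TMM-adjusted library size, as mean ± SD. A gene was counted as non-overlapping where all 3 libraries of a treatment lay on the same side of all 3 of the other.

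There were 24 gene lists, 5 primary and 19 secondary. The primary lists were secreted type 2 effectors, mTORC1 components, glycolysis, neuropeptide and neurotransmitter receptors, and cell cycle. The secondary lists were ILC2 identity, alarmin and cytokine receptors, activation and checkpoint molecules, effector transcription factors, cholesterol synthesis, fatty acid synthesis, lipid uptake and oxidation, amino acid and ATF4 genes, pentose phosphate and nucleotide synthesis, respiratory chain, tricarboxylic acid cycle, ribosome biogenesis, ribosomal proteins, tRNA synthetases and translation, unfolded protein response, interferon response, migration and residency, immediate early and stress genes, and apoptosis and survival. A further 13 lists held markers of T cells, B and plasma cells, NK cells and ILC1, ILC3, macrophages and monocytes, dendritic cells, neutrophils, eosinophils, mast cells and basophils, epithelium, endothelium, fibroblasts and erythroid cells. Mars1 was matched by its older symbol Mars, and Nmur2, Klra4, Klra8, Ly6g, Cxcr2, Slc4a1 and Ahsp were not in the table. Lists of at least 3 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 24 lists together and over the marker lists separately, and again with an estimated correlation and with fry. Counts adjusted over the list alone used Benjamini-Hochberg within each list. Where no member of a list is said to have fallen, none had an unadjusted edgeR p under 0.05 or was called by DESeq2 or voom in that direction, unless stated.

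Genes were named by a fixed rule. It took 15 genes whatever their result, and the 10 largest log2 fold changes in each direction among called, non-overlapping genes with a mean of at least 20 CPM in the higher group, leaving out unnamed gene models and receptor segments. It also took from each list up to 3 called members with the smallest adjusted p in the direction with more calls and 1 in the other direction, or the member with the smallest p where none was called. This gave 142 genes, some of which are not reported here, and any other gene is said to have been chosen after its values were seen.

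The deposited FPKM were tested with limma (trend and robust options) on log2(FPKM + 1) for genes with a mean FPKM of at least 1. Library composition was compared by exact permutation tests, two-sided, whose smallest p for 3 against 3 is 0.1. Principal components used log2 CPM with a prior count of 2 and the 500 most variable genes. Chi-square values per degree of freedom between all pairs of libraries were at least 6.04, so no library duplicated another. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

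The procedure was tested on simulated data drawn from the means and sizes of these libraries. For papain against PBS with 12534 genes, 21.5% of 65 genes changed 1.5-fold, 54.3% of 70 changed 2-fold and 92.3% of 65 changed 4-fold were called, with 7 false calls (5.9% of calls). Far fewer genes were changed in the simulation than were called in the data, so the recovery in the data may be higher. A simulated changed list of 30 genes among 12918 gave a camera p of 2.77e-128, and 1 of 20 unchanged lists had a p under 0.05. The simulated genes were drawn independently. These values therefore do not cover lists whose genes are correlated, such as cell cycle with an estimated correlation of 0.253.

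The alternatives were RLE and upper quartile scaling, no filter on low counts, a filter of at least 5 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, limma voom with sample weights, DESeq2 1.42.0, limma on FPKM, and glmTreat against a log2 fold change of 1. For FPKM they were a pseudocount of 0.1, no filter, the block and each library left out. Alternatives added after the data were seen were those of the marker lists, the recomputed FPKM, and removal of trends on length or GC content from the respiratory chain list with a loess span of 0.5. Reads, transcripts and splicing were not analysed here.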

Results

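The data were gene expression profiles of group 2 innate lymphoid cells (ILC2s) sorted from mouse lung. ILC2s are tissue-resident lymphocytes that lack antigen receptors and secrete type 2 cytokines. Mice had received PBS, the vehicle control, or papain, a plant protease that acts as an allergen in the airway. Each treatment had 3 libraries, numbered 1 to 3, made as full-length cDNA from small amounts of RNA. Total gene counts lay between 6552173 and 8082556 per library, and 28912 genes were listed. Totals were 8082556, 6836242 and 6855264 in the PBS libraries and 7956260, 8073640 and 6552173 in the papain libraries. The labels do not say whether the replicates came from separate animals, so each p-value measures the spread between these samples only, which may be technical.

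Papain was compared with PBS to ask which genes differ in ILC2s after allergen exposure, and the series title directed attention to mTORC1 and to NMUR1, a receptor for the neuropeptide neuromedin U. The type 2 cytokine transcripts Il5 and Il13 were 3.47-fold and 4.22-fold higher after papain (log2 fold changes 1.80 ± 0.15 and 2.08 ± 0.19, SE, n = 3 per group), and Areg, which encodes the growth factor amphiregulin, was 2.93-fold higher. Of 50 cell cycle genes 46 rose, with a median log2 fold change of 3.12 (camera adjusted p = 7.29e-50, adjusted p = 0.0835 with an estimated correlation). Of 56 respiratory chain genes 48 rose, with a median of 0.79 (adjusted p = 1e-19, adjusted p = 0.098 with an estimated correlation), or 0.440 with the trend of folds on gene length removed. Of 31 immediate early and heat shock genes 22 fell, with a median of -1.10 (adjusted p = 4.11e-21, adjusted p = 0.0607 with an estimated correlation). Nmur1 did not pass the test, and Mtor, which encodes the kinase of mTORC1, was 1.67-fold lower.

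By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4392 of 12918 genes tested had an adjusted p under 0.05, of which 2493 were higher and 1899 lower after papain. At least 2-fold changes were found for 1819 of them, 1090 higher and 729 lower. The 3 papain libraries lay entirely above or below the 3 PBS libraries for 4327 of the called genes, and for 6262 genes (48.5%) of all those tested, where chance gives 10%. The balance of directions moved with the scaling of the libraries. Upper quartile factors placed the median gene at -0.10 on the log2 scale, against -0.01 with TMM, and gave 2161 higher and 2417 lower genes. The first principal component of the 500 most variable genes held 68.3% of the variance and separated the treatments, and the second held 15.7%. Spearman correlations across genes were 0.961 to 0.978 within treatments and 0.898 to 0.919 between them, and genes are not independent replicates.

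**Figure D1:**
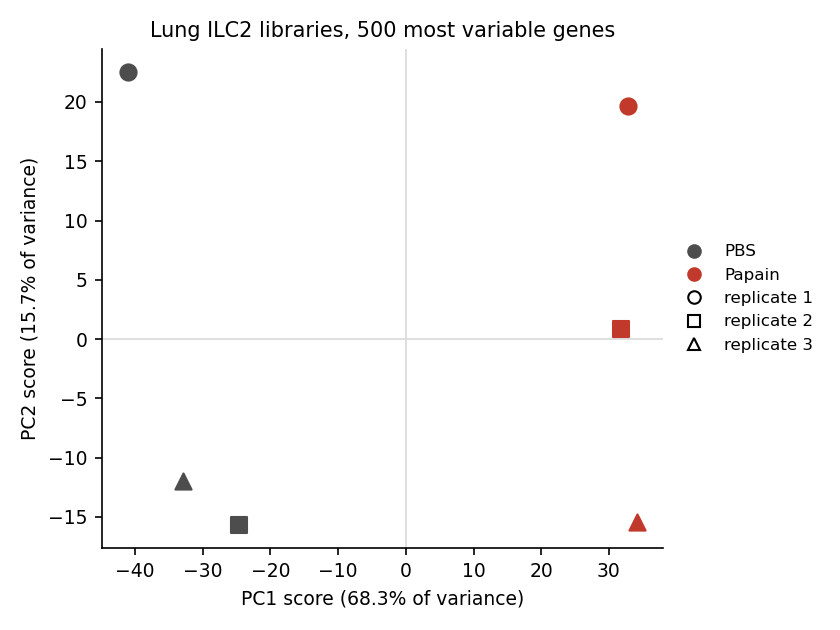
Scores of the 6 libraries on the first and second principal components of the 500 most variable genes (log2 CPM, arbitrary score units), with PBS in grey, papain in red and the marker shape giving the replicate number. The horizontal axis holds 68.3% of the variance, and all 3 papain libraries lie to the right of all 3 PBS libraries.

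The list of secreted effectors passed the test upward (camera adjusted p = 0.000609, adjusted p = 0.108 with an estimated correlation). Of 26 tested genes of cytokines, chemokines and other effectors of activated ILC2s, 14 rose, 6 fell and 6 did not pass the test (15 and 6 adjusted over the list alone). The 14 include Retnla (log2 fold change 8.82), which is weighed with the macrophage markers below, so the list may not measure ILC2 products alone. The list median was 0.50. Il5, the eosinophil growth factor, had 739 ± 53.1 CPM (counts scaled to library size) in PBS and 2566 ± 587 in papain libraries (SD, n = 3, adjusted p = 7.79e-06). Il13 had 15.7 ± 3.45 and 66.0 ± 7.50 CPM (adjusted p = 1.69e-05). Areg had 1070 ± 168 and 3137 ± 290 CPM (adjusted p = 5.74e-06). Arg1, which encodes arginase 1, had 445 ± 136 and 1540 ± 236 CPM (adjusted p = 0.000371). Penk, the proenkephalin gene, was 24.3-fold higher and Cxcl3, a neutrophil-attracting chemokine, 5.59-fold higher. Il9 rose from 8 counts in the PBS libraries together to 136 in the papain libraries (log2 fold change 4.07 ± 0.86, adjusted p = 0.00391), and the value was 4.78 without PBS replicate 1. Il2, a lymphocyte growth factor, fell by 1.54 on the log2 scale (adjusted p = 5.46e-06). The list median was 0.78 without PBS replicate 1 and 0.84 without PBS replicate 2.

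Il4 and Csf2 did not pass the test. Il4 had 28.1 ± 2.57 CPM in PBS and 31.1 ± 14.9 in papain libraries (SD, n = 3), with a log2 value of 0.15 ± 0.29 (SE, adjusted p = 0.743), which was -0.31 without papain replicate 1. Csf2, which encodes GM-CSF, had 1026 ± 104.5 and 1308 ± 262.9 CPM and a log2 value of 0.35 ± 0.14 (SE, adjusted p = 0.0668). It passed the threshold with no filter (adjusted p = 0.00191), with voom (0.0269) and with DESeq2 (0.0245), and also without PBS replicate 1 (0.042, log2 value 0.44) and without papain replicate 3 (0.0115, log2 value 0.50), and its adjusted p ran from 0.00191 to 0.284 over the alternatives. In the GENCODE M21 annotation of GRCm38 (mm10), Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669, minus strand), Il13 (ENSMUSG00000020383, 53631324 to 53634702, minus strand), Il5 (ENSMUSG00000036117, 53720794 to 53725106, plus strand) and Csf2 (ENSMUSG00000018916, 54247271 to 54249667, minus strand) are protein-coding neighbours in the type 2 cytokine region. Areg (ENSMUSG00000029378) lies on chromosome 5 from 91139599 to 91148432 and Il9 (ENSMUSG00000021538) on chromosome 13 from 56479277 to 56482246. Csf2 overlaps the antisense gene Gm12223, which had 240 counts over the 6 libraries against 51883 for Csf2, and reads of such partners cannot be told apart without strand. Il5 overlaps the antisense gene Gm12214, which had 0 counts.

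**Figure D2:**
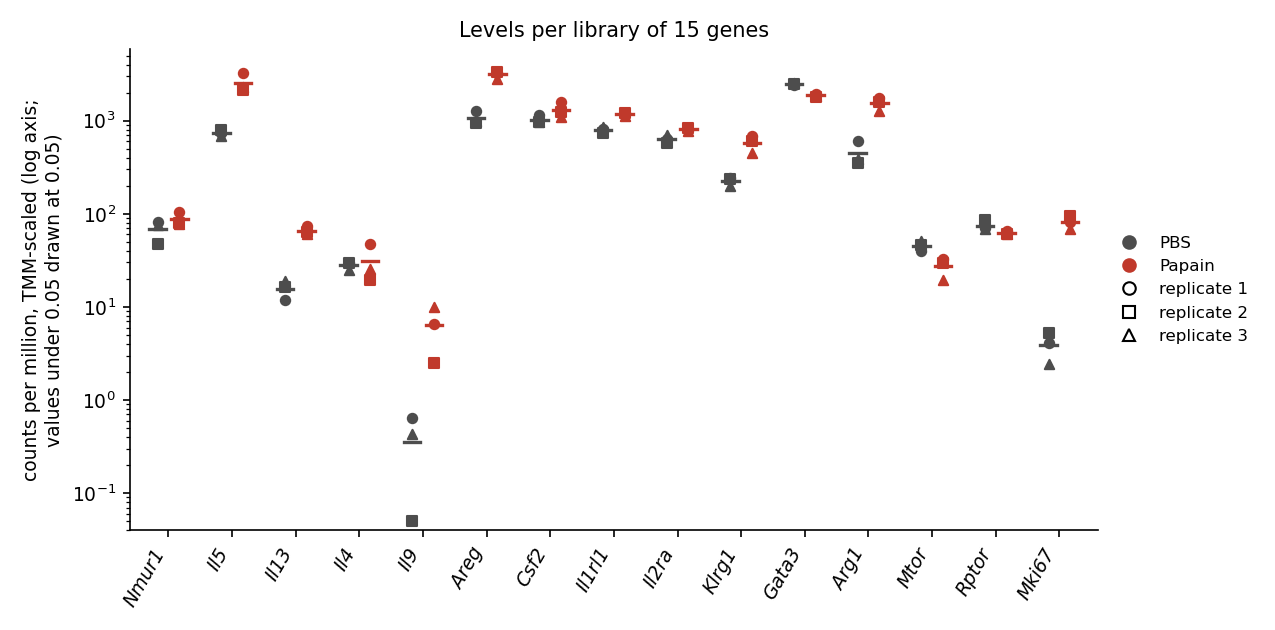
CPM (TMM-scaled, logarithmic axis) of the 15 genes fixed for reporting, in each of the 3 PBS (grey) and 3 papain (red) libraries, with horizontal bars at the group means. Il5, Il13, Areg, Klrg1, Arg1 and Mki67 show no overlap between treatments, while Nmur1, Il4 and Csf2 do.

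Receptors for neuropeptides and neurotransmitters went both ways. Nmur1 (ENSMUSG00000026237, chromosome 1, 86386303 to 86426228, minus strand) had 68.7 ± 18.3 CPM in PBS and 87.1 ± 15.2 in papain libraries (SD, n = 3), a log2 value of 0.34 ± 0.20 (SE) with an adjusted p of 0.212 and overlapping groups. Of 17 tested receptors of this list 2 rose, 4 fell and 11 did not pass the test (2 and 4 adjusted over the list alone). Ramp3, a partner of the receptors for adrenomedullin and amylin, was 1.63-fold lower (adjusted p = 0.000441) and Adora2a, an adenosine receptor, was 1.63-fold lower (adjusted p = 0.000825). Ramp1, which with Calcrl forms the receptor for calcitonin gene-related peptide, rose 1.78-fold (adjusted p = 0.000692). The list median was 0.25, its mean was -0.01 and camera's direction was down, with an adjusted p of 0.578, and adjusted p = 0.813 with an estimated correlation. The median was -0.10 without papain replicate 1.

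The genes of mTORC1, the nutrient-sensing kinase complex, and of its upstream sensors and direct effectors also went both ways. Of 48 tested, 12 rose, 12 fell and 24 did not pass the test, with 12 and 12 adjusted over the list alone. The median was -0.09, the mean 0.03 and camera's direction down, with an adjusted p of 0.758, and adjusted p = 0.85 with an estimated correlation. Mtor (ENSMUSG00000028991, chromosome 4, 148448611 to 148557683, plus strand) fell from 45.6 ± 5.70 to 27.3 ± 6.93 CPM (SD, n = 3, log2 fold change -0.74 ± 0.21, SE, adjusted p = 0.0181). This call was lost without PBS replicate 2 (adjusted p = 0.0539), without PBS replicate 3 (adjusted p = 0.0783) and without papain replicate 3 (adjusted p = 0.054), in a range of 0.00357 to 0.0783 over the alternatives. Rptor (ENSMUSG00000025583, chromosome 11, 119602905 to 119899576, plus strand), which encodes the mTORC1 subunit RAPTOR, had 74.4 ± 9.36 and 62.1 ± 2.99 CPM and a log2 value of -0.26 ± 0.13 (SE, adjusted p = 0.156). Lamtor5 and Lamtor1, subunits of the Ragulator complex that holds mTORC1 at the lysosome, rose 2.01-fold (adjusted p = 0.000123) and 1.89-fold (adjusted p = 0.000171). Of the sestrins, stress proteins that restrain mTORC1, Sesn3 rose 2.24-fold (adjusted p = 0.000224) and Sesn1 was 2.00-fold lower (adjusted p = 0.000247). Transcript levels do not measure the activity of the kinase.

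Cell cycle genes rose together. Of 50 genes of DNA synthesis and mitosis 46 rose, 1 fell and 3 did not pass the test, with 47 and 1 adjusted over the list alone, and the camera adjusted p was 7.29e-50 (adjusted p = 0.0835 with an estimated correlation). Mki67, the gene of the proliferation antigen Ki-67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand), rose from 3.91 ± 1.39 to 82.1 ± 13.8 CPM (SD, n = 3, 20.9-fold, adjusted p = 1.07e-06). Rrm2, a subunit of ribonucleotide reductase, rose 24.5-fold (adjusted p = 8.68e-08). Ccna2, the cyclin A2 gene, rose from 18 counts in PBS to 1463 in papain libraries (log2 fold change 6.29 ± 0.30, adjusted p = 4.25e-07). Ccnd2, the cyclin D2 gene, fell by 0.40 on the log2 scale (adjusted p = 0.0118). That call was lost without PBS replicate 2 (adjusted p = 0.0525) and without papain replicate 1 (adjusted p = 0.054), in a range of 0.000667 to 0.054 over the alternatives. Other proliferation genes were among the 10 largest increases, namely Aurkb (9 against 704 counts, log2 fold change 6.19), the PCNA-associated factor gene Pclaf (38 against 2679 counts, 6.08), Birc5 (38 against 1682 counts, 5.40) and Cdca8 (29 against 1041 counts, 5.11). Without PBS replicate 2 the log2 values were 6.88 for Ccna2, 7.16 for Aurkb and 7.74 for Pclaf. Ccna2 and Cdca8 overlap genes on the opposite strand that had 719 and 419 counts, so part of their counts is uncertain.

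The other large increases were Retnla, Il1r2, Chil3, Mmp10 and Zbtb32. Il1r2, the decoy receptor for interleukin 1, rose from 1.44 ± 0.63 to 368 ± 73.9 CPM (SD, n = 3, 256-fold, SE of the log2 fold change 0.26, adjusted p = 5.08e-08). Retnla, which encodes the secreted protein RELM-alpha, had 11 counts in PBS and 4901 in papain libraries (log2 fold change 8.82 ± 1.31, adjusted p = 0.00677). Of these counts 3230 were in papain replicate 3, without which the log2 value was 7.72, and limma voom with sample weights gave an adjusted p of 0.257, in a range of 2.8e-19 to 0.257. Chil3, a chitinase-like protein gene that is also a macrophage marker, rose from 3.07 ± 1.97 to 426 ± 160 CPM (log2 fold change 7.10 ± 0.54, adjusted p = 0.000301), and it is uncertain because reads can be shared with the near-identical Chil4. Mmp10, a matrix metalloproteinase gene, had 7 against 854 counts (log2 fold change 6.80, with 6.20 without PBS replicate 1 and 7.43 without PBS replicate 3). Zbtb32, a transcriptional repressor gene, had 4 against 492 counts (6.78, with 8.02 without PBS replicate 2).

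The 10 largest decreases held no member of the gene lists. AI593442 fell from 463 to 44 counts (log2 fold change -3.41 ± 0.35, adjusted p = 3.15e-05). Ciart, a circadian repressor gene, fell by 2.91 (adjusted p = 0.00215), and the reticulon gene Rtn2 by 2.90 (adjusted p = 7.75e-05). Flrt2, a cell adhesion gene, fell from 61.7 ± 8.39 to 8.43 ± 4.89 CPM (SD, n = 3, log2 fold change -2.86, and -3.45 without papain replicate 2). Mapk12, the p38 gamma kinase gene, fell from 69.9 ± 7.97 to 10.3 ± 0.38 CPM (log2 fold change -2.76, adjusted p = 1.34e-06). The anion transporter gene Slc26a11 fell by 2.85, Cfap45 by 2.72, Gprin3 by 2.61, the cadherin gene Cdh23 by 2.57 and Fam71a by 2.54, with adjusted p-values between 3.18e-05 and 0.000365. Cfap45 overlaps a gene on the opposite strand that had 70 counts against its 1537.

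Of 25 genes of glucose uptake, glycolysis and lactate export 13 rose, 1 fell and 11 did not pass the test (13 and 2 adjusted over the list alone), with a median of 0.62 and an adjusted p of 6.01e-05 (adjusted p = 0.108 with an estimated correlation). Pgam1 rose 5.01-fold (adjusted p = 4.38e-06), Pgk1 2.69-fold (adjusted p = 1.09e-05) and the pyruvate kinase gene Pkm 1.88-fold, from 921 ± 55.5 to 1731 ± 107.6 CPM (SD, n = 3, adjusted p = 2.36e-05). Pdk1, whose kinase inhibits pyruvate dehydrogenase, fell by 0.88 on the log2 scale (adjusted p = 0.00167). Of 56 nuclear-encoded subunits of the respiratory chain and ATP synthase, 48 rose, none fell and 8 did not pass the test (50 rose adjusted over the list alone), among them Sdhb (2.31-fold, adjusted p = 5.37e-06), Cox7a2 (2.00-fold, adjusted p = 1.45e-05) and Ndufv2 (2.53-fold, adjusted p = 1.63e-05). The adjusted p of that list was 1e-19 (adjusted p = 0.098 with an estimated correlation), and its median of 0.79 was 0.440 with the trend on length removed, a test chosen after the result was seen. Of 22 tricarboxylic acid cycle genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.65 and an adjusted p of 5.78e-05 (adjusted p = 0.152 with an estimated correlation). Citrate synthase, Cs, rose 2.30-fold and Mdh1 1.74-fold, while Dlst fell by 0.38 (adjusted p = 0.0233). The Dlst call was lost without PBS replicate 1 (adjusted p = 0.0936), papain replicate 1 (0.0833) and papain replicate 3 (0.0568) and with FPKM (0.0609), and its range over the alternatives was 0.00629 to 0.0936.

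The 5 lists of lipid and biosynthetic genes passed the test upward, with medians of 0.37 to 0.72, and lost the call with an estimated correlation. The trend of folds on gene length was not removed from these lists, so how much of their rise follows length was not tested. Of 23 sterol synthesis genes 12 rose and none fell (13 adjusted over the list alone, median 0.72, adjusted p = 0.000645, adjusted p = 0.153 with an estimated correlation). Ebp, a sterol isomerase gene, rose 2.27-fold and Insig1, a regulator of sterol synthesis, 2.22-fold. Of 18 fatty acid synthesis genes 8 rose and none fell by edgeR (2 fell at an unadjusted p under 0.05, 1 by voom and 0 by DESeq2, and 8 rose and 1 fell adjusted over the list alone, median 0.39, adjusted p = 0.0473, adjusted p = 0.153 with an estimated correlation). Elovl1 rose by 1.35, Scd2 by 1.48 and the citrate carrier gene Slc25a1 by 1.14 on the log2 scale, and the list's adjusted p was 0.0706 without papain replicate 3, in a range of 0.000203 to 0.153. Of 23 genes of lipid uptake, storage and oxidation 12 rose and none fell (15 adjusted over the list alone, median 0.64, adjusted p = 4.46e-06, adjusted p = 0.129 with an estimated correlation). Fabp5, a fatty acid binding protein gene, rose 6.85-fold, the lipid droplet gene Plin2 3.30-fold, and Dgat1, which makes triglyceride, 1.80-fold from 1203 ± 82.9 to 2160 ± 51.9 CPM (SD, n = 3). Of 26 amino acid transport and one-carbon genes 12 rose and 3 fell (13 and 6 adjusted over the list alone, median 0.66, adjusted p = 0.01, adjusted p = 0.268 with an estimated correlation). The mitochondrial folate enzyme gene Mthfd2 rose 9.51-fold and the serine synthesis genes Phgdh and Psat1 2.34-fold and 4.44-fold, while the amino acid transporter gene Slc38a2 was 1.77-fold lower. Of 24 pentose phosphate and nucleotide synthesis genes 10 rose and none fell (10 adjusted over the list alone, median 0.37, adjusted p = 0.00507, adjusted p = 0.153 with an estimated correlation), with Paics 2.12-fold, Nme1 2.40-fold and Tkt 1.80-fold higher.

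Receptors and surface molecules of activation rose more often than they fell. Of 31 alarmin, cytokine and lipid mediator receptors 15 rose and 9 fell (16 and 10 adjusted over the list alone, median 0.31, adjusted p = 0.00652, adjusted p = 0.108 with an estimated correlation). Il1rl1, the gene of the IL-33 receptor ST2 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415, plus strand), rose 1.47-fold from 802 ± 58.4 to 1181 ± 41.1 CPM (SD, n = 3, adjusted p = 0.000581). Il2ra (CD25, ENSMUSG00000026770, chromosome 2, 11642807 to 11693193, plus strand) rose 1.27-fold (adjusted p = 0.0157), a call lost without PBS replicate 2 (adjusted p = 0.0738) and without papain replicate 2 (adjusted p = 0.0796), in a range of 0.00206 to 0.0796. Tnfrsf4 (OX40) rose 12.8-fold and the leukotriene receptor gene Cysltr2 4.07-fold, while the prostaglandin E2 receptor gene Ptger4 was 2.26-fold lower. Of 25 activation and co-inhibitory molecules 14 rose and 4 fell (16 and 4 adjusted over the list alone, median 0.61, adjusted p = 3.89e-07, adjusted p = 0.0835 with an estimated correlation). Tnfsf4 (OX40 ligand) rose 20.5-fold from 6.13 ± 0.68 to 126 ± 27.1 CPM and the checkpoint gene Ctla4 rose by 4.32 on the log2 scale from 6.99 ± 0.81 to 140 ± 41.7 CPM. Cd69, an early activation and retention marker, fell from 3795 ± 500 to 1344 ± 112 CPM (adjusted p = 4.06e-06).

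Genes that mark ILC2s went both ways. Of 29 tested, 13 rose and 10 fell (13 and 12 adjusted over the list alone), with a median of 0.04, which turned negative with upper quartile factors, and an adjusted p of 0.625 (adjusted p = 0.85 with an estimated correlation). Gata3, the defining transcription factor (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034, minus strand), fell 1.33-fold from 2480 ± 76.2 to 1867 ± 61.7 CPM (SD, n = 3, adjusted p = 0.00243). Klrg1, a marker of mature and activated ILC2s (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882, minus strand), rose 2.58-fold from 226 ± 24.5 to 583 ± 126 CPM (adjusted p = 6.99e-05). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand) is also in this list. Tph1, the first enzyme of serotonin synthesis, rose 4.65-fold, Ly6a (Sca-1) 6.49-fold and the transcription factor gene Nfil3 3.37-fold. Of 32 transcription factors of activation and quiescence 10 rose, 11 fell and 11 did not pass the test (11 and 11 adjusted over the list alone), with a median of -0.11, a mean of 0.06 and camera's direction up (adjusted p = 0.807, adjusted p = 0.903 with an estimated correlation). Camera's direction was down without PBS replicate 2 (adjusted p = 0.864) and without papain replicate 1 (adjusted p = 0.979), in a range of 0.193 to 0.994 over the alternatives. Irf4, a factor of lymphocyte effector differentiation, rose 12.3-fold from 16.8 ± 2.58 to 208 ± 32.4 CPM. Zfp36, which destabilises cytokine mRNA, was 5.51-fold lower, the transcription factor gene Myc 2.63-fold lower and the quiescence factor Klf2 3.96-fold lower. Zfp36 is also in the immediate early and stress list.

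Genes of protein production moved unevenly. Of 33 tRNA synthetase and translation factor genes 19 rose and 4 fell (19 and 4 adjusted over the list alone, median 0.44, adjusted p = 0.00311, adjusted p = 0.268 with an estimated correlation), with Gars 2.62-fold, Eif4a1 1.69-fold and Eif2s1 1.91-fold higher and Vars 1.51-fold lower. Of 25 endoplasmic reticulum chaperone and unfolded protein response genes 16 rose and 4 fell (16 and 5 adjusted over the list alone, median 0.47, adjusted p = 0.000547, adjusted p = 0.241 with an estimated correlation). Dnajb11 rose 2.41-fold, Sec61b 2.48-fold and Manf 2.53-fold, while the chaperone gene Hspa5 fell from 4694 ± 1230 to 2202 ± 178 CPM (SD, n = 3, adjusted p = 0.000493). Of 44 ribosome assembly genes 5 rose and 8 fell (5 and 8 adjusted over the list alone, median -0.25, adjusted p = 0.107, adjusted p = 0.469 with an estimated correlation). Gnl3 was 1.97-fold lower, Ppan 1.72-fold lower and Nop56 1.57-fold lower, and Nhp2 was 2.46-fold higher. This list passed the threshold without papain replicate 2 (adjusted p = 0.0318), in a range of 0.0318 to 0.469. Of 77 ribosomal protein genes 14 rose and 5 fell (13 and 5 adjusted over the list alone), with a median of 0.05 that turned negative with upper quartile factors and an adjusted p of 0.758 (adjusted p = 0.903 with an estimated correlation). Camera's direction for this list was up, and down without PBS replicate 1 (adjusted p = 0.991, in a range of 0.0464 to 0.994). Rps26 rose by 0.73, Rpl10 by 0.53 and Rpl28 by 0.58 on the log2 scale, and Rps27 was 1.74-fold lower, all uncertain because processed pseudogenes share their sequence.

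Interferon-stimulated genes rose in part, unevenly between libraries. Of 29 tested 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 1.07, adjusted p = 0.00111, adjusted p = 0.469 with an estimated correlation), and the median was 0.58 without papain replicate 3 (adjusted p = 0.0161, in a range of 1.37e-09 to 0.469), the library with the highest levels of several macrophage markers such as Lyz2 and Cd14. The chemokine gene Cxcl10 rose 2.45-fold, Oas3 5.57-fold and Zbp1 3.24-fold, and Socs1, which restrains cytokine signalling, was 2.14-fold lower. Mx1, singled out after its values were seen, had 0 counts in PBS and 152 in papain libraries, at least 50.0-fold higher against a floor of 3 counts over the group, and the list median was also 1.07 with Mx1 at that bound. Of 23 trafficking and retention receptors 11 rose and 3 fell (11 and 4 adjusted over the list alone, median 0.39, adjusted p = 0.0242, adjusted p = 0.153 with an estimated correlation). Ccr7, the lymph node homing receptor, rose 10.6-fold from 20.8 ± 6.07 to 221 ± 29.9 CPM (SD, n = 3), Itgae (CD103) 16.9-fold and Itgb1 2.27-fold. Of 22 BCL2 family and caspase genes 8 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.447, adjusted p = 0.469 with an estimated correlation). Bcl2a1d rose 2.59-fold, uncertain because its paralogs are near-identical, Fas rose 2.35-fold and the survival gene Bcl2 was 1.76-fold lower. Bak1 had 1 count in PBS and 68 in papain libraries (adjusted p = 0.00191), a ratio of 67.1 with a 95% exact interval of 11.6 to 2690 for counting error only. Its log2 fold change rested on PBS replicate 1, which held that count, and was 5.61 with it and 7.46 without it.

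**Figure D3:**
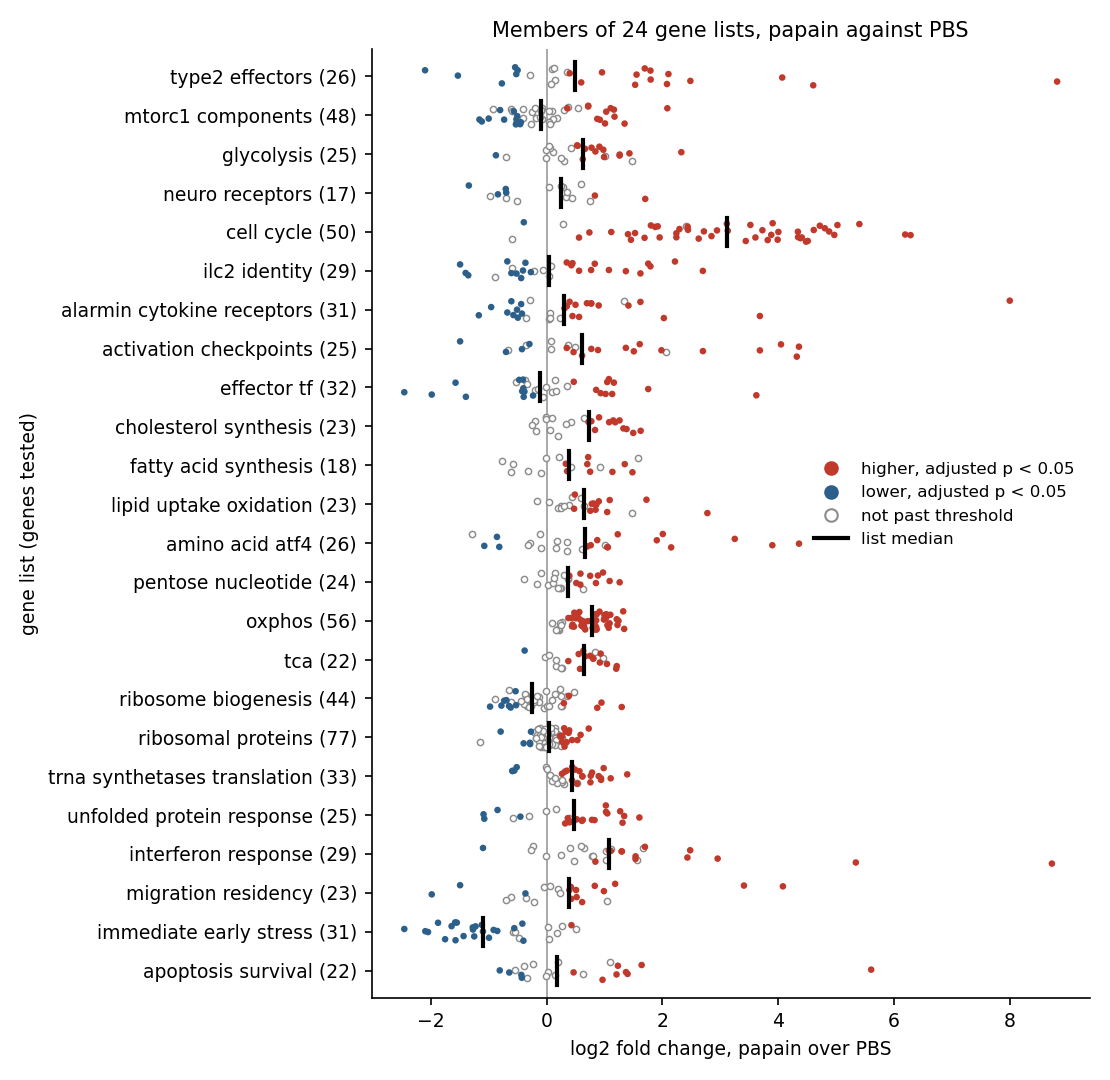
Log2 fold changes, papain over PBS, of the tested members of the 24 gene lists (1 point per gene, filled where the adjusted p was under 0.05), with a black bar at each list's median. Cell cycle genes have a median of 3.12 and immediate early and heat shock genes a median of -1.10. The fitted value of Mx1, at the far right of the interferon list, depends on the prior count, since Mx1 had 0 counts in PBS.

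Immediate early and heat shock genes, which stimulation and tissue dissociation induce, were the 1 called list whose direction was down. Of 31 tested 22 fell, 1 rose and 8 did not pass the test, with 24 and 2 adjusted over the list alone, and the adjusted p was 4.11e-21 (adjusted p = 0.0607 with an estimated correlation). Fos fell from 9965 ± 1304 to 2404 ± 192 CPM (SD, n = 3, adjusted p = 7.24e-07), Dusp1 from 5438 ± 907 to 1270 ± 117 CPM and Jun from 3442 ± 370 to 936 ± 119 CPM. Socs3 rose 1.35-fold with an adjusted p of 0.0493, a call lost without PBS replicate 1 (0.148), PBS replicate 2 (0.0716), papain replicate 2 (0.158) and papain replicate 3 (0.118), and with RLE (0.0502), upper quartile factors (0.121), voom (0.0507) and FPKM (0.0866), in a range of 0.00795 to 0.158. The list took 7.52 ± 0.72% of counts in PBS and 2.96 ± 0.15% in papain libraries (exact permutation p = 0.1, two-sided). That p is the smallest that 3 against 3 libraries can give.

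Other measures of RNA and library quality moved with treatment in part. Genes detected numbered 19649, 23983 and 19720 in PBS and 17928, 18090 and 17904 in papain libraries (exact permutation p = 0.1, two-sided). The 10 most abundant genes took 8.01 ± 0.72% and 5.59 ± 0.19% of counts (SD, n = 3, exact permutation p = 0.1), and the nuclear RNAs Malat1 and Neat1 0.147 ± 0.0174% and 0.0699 ± 0.0167% (exact permutation p = 0.1). Protein-coding genes took 96.7 ± 0.25% and 97.6 ± 0.085% (exact permutation p = 0.1). Mitochondrial genes took 1.16 ± 0.15% and 1.23 ± 0.15% (exact permutation p = 0.6), and ribosomal protein genes 5.27 ± 0.22% and 5.25 ± 0.099% (exact permutation p = 0.9). PBS replicate 2 stood apart, with the most genes detected and 88.8 CPM in olfactory and vomeronasal receptor genes, against 45.9 and 46.5 CPM in the other PBS libraries and 19.9 to 27.2 in papain libraries.

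Markers of other cells were tested because a sort of lung ILC2s can hold them. Of 16 macrophage and monocyte markers 7 rose and none fell (7 adjusted over the list alone, median 2.02, adjusted p = 0.00692, adjusted p = 0.949 with an estimated correlation), with Chil3, the lipopolysaccharide co-receptor gene Cd14 (6.05-fold, adjusted p = 0.000759) and Cd68 (2.23-fold, adjusted p = 0.00675). Of 10 dendritic cell markers 6 rose and none fell (8 adjusted over the list alone, median 1.65, adjusted p = 0.000942, adjusted p = 0.77 with an estimated correlation), with Ccr7, Irf8 (2.93-fold, adjusted p = 0.000917) and the MHC class II gene H2-Eb1 (2.88-fold, adjusted p = 0.0038). Activated lymphocytes can also express Ccr7, Irf8 and MHC class II genes. Papain replicate 3 had the highest levels of several such genes, for example Lyz2 with 669.9 CPM against 107.6 to 345.2 CPM in the other libraries, an example chosen after its values were seen.

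Granulocyte markers were tested as well. Of 3 tested neutrophil markers S100a9 (5 counts in PBS, log2 fold change 4.58) and S100a8 (5 counts in PBS, 4.50) rose (2 adjusted over the list alone, list adjusted p = 0.435, adjusted p = 0.949 with an estimated correlation). S100a9 had a log2 value of 5.29 without PBS replicate 3 and 3.51 without papain replicate 3, and S100a8 had 3.91 without PBS replicate 1 and 8.39 without PBS replicate 3. Of 2 tested eosinophil markers Ear2 rose (7 against 194 counts, log2 fold change 4.76, with 5.92 without PBS replicate 2 and 4.13 without papain replicate 3), both rose adjusted over the list alone, and the list was too small for a set test. Of 6 mast cell and basophil markers Cyp11a1, Cpa3 and Fcer1a rose (4 adjusted over the list alone, list adjusted p = 0.236, adjusted p = 0.949 with an estimated correlation). The list passed the threshold without PBS replicate 2 (adjusted p = 0.00801, in a range of 0.00801 to 0.949). Cyp11a1 had 17 against 448 counts (log2 fold change 4.67, with 4.06 without PBS replicate 1 and 7.06 without PBS replicate 2), and the mast cell protease gene Cpa3 was 1.99-fold higher, at 32.0 ± 4.22 and 63.4 ± 20.7 CPM (SD, n = 3). Fcer1a, part of the IgE receptor, had 11 against 100 counts (log2 fold change 3.07, with 2.47 without PBS replicate 1 and 3.91 without PBS replicate 2). Its adjusted p of 0.0193 was over 0.05 without PBS replicate 3 (0.0637), papain replicate 1 (0.0626) and papain replicate 2 (0.0728), in a range of 0.00148 to 0.0728.

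Lymphocyte markers other than those of ILC2s changed singly. Of 13 T cell markers 2 rose and 1 fell (2 and 1 adjusted over the list alone), the median was 0.11, the mean 0.12 and camera's direction down (adjusted p = 0.95, adjusted p = 0.971 with an estimated correlation), with the direction up without PBS replicate 1 (adjusted p = 0.955) and papain replicate 3 (0.724), in a range of 0.621 to 0.993. Cd3g rose 1.35-fold (adjusted p = 0.00931), Cd247 rose 1.96-fold (adjusted p = 0.02) and Tcrg-C1 was 2.41-fold lower (adjusted p = 0.000852). The call of Cd247 was lost without PBS replicate 1 (0.0693), PBS replicate 2 (0.0547), papain replicate 1 (0.0571) and papain replicate 2 (0.109), in a range of 0.00101 to 0.109. Of 6 B and plasma cell markers 2 rose and 1 fell (2 and 1 adjusted over the list alone, list adjusted p = 0.712, adjusted p = 0.971 with an estimated correlation). Cd79a had 29 against 132 counts (log2 fold change 2.19, with 2.78 without PBS replicate 1, adjusted p = 0.0209), and its call was lost without PBS replicate 3 (0.0591) and papain replicate 3 (0.0521), in a range of 0.00309 to 0.0591. Igkc rose 2.85-fold (adjusted p = 0.0302), lost without PBS replicate 1 (0.0572), PBS replicate 3 (0.068), papain replicate 2 (0.111) and papain replicate 3 (0.0568), in a range of 0.00617 to 0.111. Ighm was 1.49-fold lower (adjusted p = 0.0198), lost without PBS replicate 1 (0.0655), papain replicate 2 (0.0897) and papain replicate 3 (0.0595), in a range of 0.0001 to 0.0897. Of 3 NK cell and ILC1 markers Gzmb, the granzyme B gene, rose 6.63-fold (1 adjusted over the list alone, list adjusted p = 0.435, adjusted p = 0.949 with an estimated correlation).

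Of 5 ILC3 markers Il17f rose 2.75-fold with overlapping groups (adjusted p = 0.039), and none rose adjusted over the list alone. Its call was lost without PBS replicate 1 (0.0839), PBS replicate 2 (0.0682), PBS replicate 3 (0.127), papain replicate 2 (0.159) and papain replicate 3 (0.118), and with upper quartile factors (0.0507), voom (0.0687) and FPKM (0.0553), in a range of 0.00412 to 0.159. The ILC3 median was -0.05, the mean 0.22 and camera's direction down (adjusted p = 0.95, adjusted p = 0.971 with an estimated correlation). The direction was up without PBS replicate 2 (0.862), papain replicate 1 (0.865) and papain replicate 3 (0.992), in a range of 0.698 to 0.993.

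Transcripts of structural lung cells were present at levels that varied within treatments. Of 14 epithelial markers 4 rose (4 adjusted over the list alone, median 1.06, adjusted p = 0.39, adjusted p = 0.971 with an estimated correlation), among them Krt19 (20 against 121 counts, 6.02-fold, adjusted p = 0.00686), Ager (2.88-fold, adjusted p = 0.0145) and Cdh1 (2.04-fold, adjusted p = 0.017). The list passed the threshold without papain replicate 1 (adjusted p = 0.0266, in a range of 0.0266 to 0.971). The call of Ager was lost without PBS replicate 3 (0.0564), in a range of 1.03e-09 to 0.0564, and that of Cdh1 without PBS replicate 1 (0.0599), PBS replicate 3 (0.0505) and papain replicate 3 (0.0696), in a range of 0.000771 to 0.0696. Sftpc, the surfactant protein C gene, chosen after its values were seen, had 426 to 1522 CPM with overlapping groups. Of 12 endothelial markers 0 passed edgeR's test, also adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 or by voom (list adjusted p = 0.835, adjusted p = 0.971 with an estimated correlation). The smallest p there was that of Pecam1 (log2 value -0.28, adjusted p = 0.372), which passed without PBS replicate 1 (adjusted p = 0.0478, in a range of 0.0478 to 0.864). Camera's direction for the endothelial list was down, and up without PBS replicate 2 (adjusted p = 0.862) and papain replicate 1 (adjusted p = 0.865), in a range of 0.236 to 0.998. Of 11 fibroblast markers 0 passed any of these tests (list adjusted p = 0.835, adjusted p = 0.971 with an estimated correlation), with the smallest p for Col1a2 (log2 value 0.97, adjusted p = 0.266, with 1.56 without PBS replicate 2), and the list's direction was down without PBS replicate 1 (adjusted p = 0.568, in a range of 0.313 to 0.992). Of 5 erythroid markers 0 passed any of them (list adjusted p = 0.508, adjusted p = 0.971 with an estimated correlation), with the smallest p for Hba-a2 (log2 value -1.45, adjusted p = 0.341, with -2.82 without papain replicate 1), and the list passed without papain replicate 1 (adjusted p = 0.0266, in a range of 0.0266 to 0.971).

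**Figure D4:**
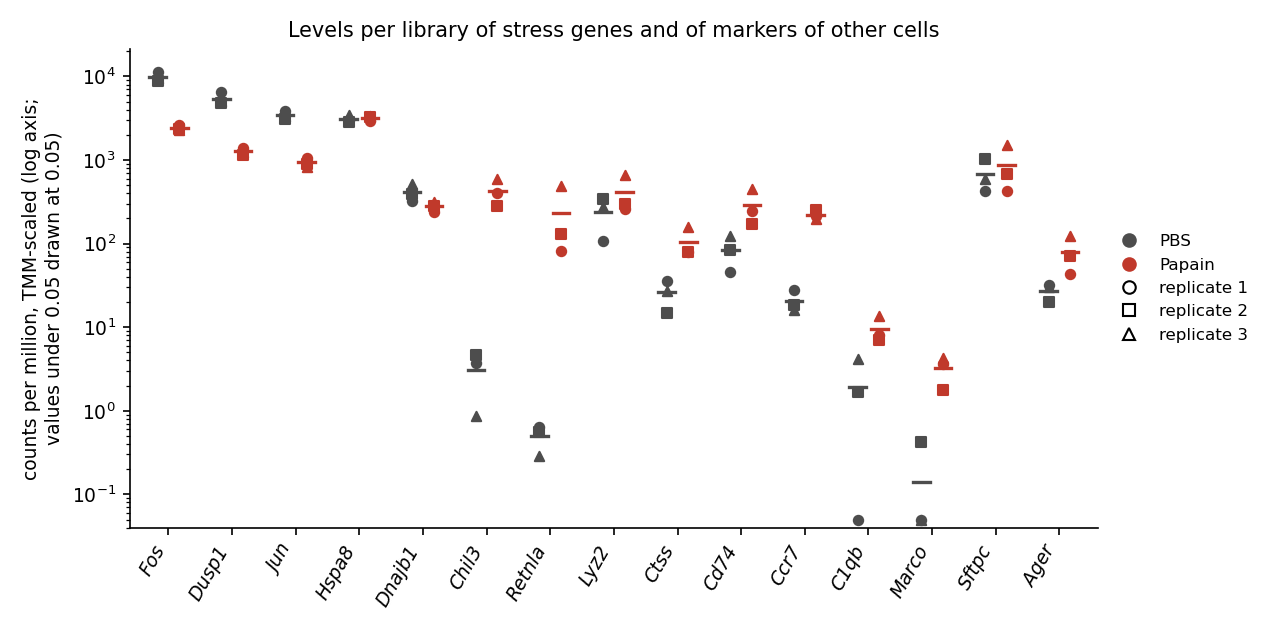
CPM (TMM-scaled, logarithmic axis) of immediate early and heat shock genes (Fos to Dnajb1) and of markers of macrophages, dendritic cells and epithelium (Chil3 to Ager), in each of the 3 PBS (grey) and 3 papain (red) libraries, with bars at the group means. The genes were picked after their values were seen. Fos fell from 9965 to 2404 CPM, and Lyz2 and Sftpc overlap between treatments.

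The deposited FPKM, a second form of the same libraries, gave similar calls. Of 11407 genes tested with limma on log2(FPKM + 1), 3998 passed an adjusted p of 0.05, 2465 higher and 1533 lower after papain. Of the 4031 genes called from counts and tested in both forms, 3623 (89.9%) were also called from FPKM, all 3623 with the same sign. Folds on this scale understate the changes of low genes. Both forms come from the same reads, so the second adds no independent samples.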

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

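Tests chosen only after the result was seen were the marker lists under these alternatives, the recomputed FPKM and the removal of trends on length or GC content. All other alternatives were planned. The count of 4392 genes (2493 higher and 1899 lower) stayed within 1.5 times, at 3316 without PBS replicate 3 to 4831 with limma voom, under every alternative but glmTreat, which asks for a log2 fold change beyond 1 and called 529 genes, 412 higher and 117 lower. DESeq2 called 4484 genes, of which 4320 were shared. The FPKM count of 3998 lay between 3014 without PBS replicate 3 and 4178 with recomputed FPKM. The labels' replicate numbers were also fitted as a replicate block, which called 4355 genes, 2465 higher and 1890 lower, with Csf2 among them (adjusted p = 0.0114, in a range of 0.00191 to 0.284) and Il17f not (0.0674, in a range of 0.00412 to 0.159). Deviations of same-numbered libraries from their group means correlated at 0.215, -0.033 and 0.124, and not every library correlated best with its own number, so the numbers were not taken as pairs.

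Of 17 called primary and secondary lists, 14 kept the call and the direction with RLE or upper quartile factors, no filter, 5 CPM, the replicate block, each library left out and voom, and all 17 passed in the same direction by fry, which tests for any change rather than a difference from other genes. With an estimated correlation none of the 17 passed by camera. Type 2 effectors had an adjusted p of 0.108, glycolysis 0.108 and cell cycle 0.0835. Among the 17, alarmin and cytokine receptors missed the threshold with voom (0.12, in a range of 6.69e-07 to 0.12), fatty acid synthesis with upper quartile factors (0.0551) and 5 CPM (0.0947, in a range of 0.000203 to 0.153), and migration with 5 CPM (0.055) and voom (0.0535, in a range of 0.000266 to 0.153). Of lists not called, with no filter ILC2 identity (0.0464, in a range of 0.0464 to 0.916), ribosomal proteins (0.0464) and apoptosis (0.0317, with 0.00704 by fry, in a range of 0.00704 to 0.806) passed, as did markers of neutrophils (0.0357), mast cells (0.0215) and epithelium (0.0357), and B cell markers by fry (0.0224), all 4 in ranges up to 0.949 or 0.971. The macrophage list missed the threshold with 5 CPM (0.0695, in a range of 7.38e-07 to 0.949). The cause was not tested.

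Lists whose direction reversed were not past the threshold there. The mTORC1 list was up with no filter (0.478) and by fry (0.685). The effector transcription factors were down with upper quartile factors (0.932), the replicate block (0.755) and voom (0.806), and leaving out 1 library gave 0.346 to 0.979. Ribosomal proteins were down with upper quartile factors (0.673), with 0.289 to 0.991 on leaving out 1 library. T cell markers were up with no filter (0.621), voom (0.788) and fry (0.819), with 0.724 to 0.979 on leaving out 1 library, and ILC3 markers were up by fry (0.924), with 0.698 to 0.992. On leaving out 1 library, endothelial markers had 0.236 to 0.979 and fibroblast markers 0.313 to 0.992. The log2 value of Il4 was -0.02 with voom and ran from -0.31 to 0.40 on leaving out 1 library. The cause was not tested. Of 135 called named genes 121 kept direction and call under the alternatives run on the lists by edgeR or voom and under DESeq2 and FPKM, where tested there, and none changed sign. FPKM covered 137 and 5 CPM 133 of all 142 named genes, and the results of glmTreat for them were left out of these counts. Depth limits the folds of genes with few PBS counts, such as Il9 with 8. The simulated data, in which far fewer genes were changed than were called here, recovered 21.5% of genes changed 1.5-fold.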

Other observations

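The families in this paragraph and the next, 20 in all, were tested only after the result was seen, and so were the shift by the most abundant genes and the trends on length and GC content. The p-values of the families do not account for that choice. They are descriptive and cannot be set against those of the planned lists. The trend on length was removed for none of these families. Of 47 genes of the proteasome and its assembly 35 rose by edgeR (median log2 fold change 0.81, camera adjusted p = 2.25e-17 over the 20 families, adjusted p = 0.0401 with an estimated correlation), and 0 fell by edgeR, DESeq2 or voom, with 1 falling at an unadjusted p under 0.05. The catalytic subunit gene Psmb5 rose from 16.3 to 74.7 CPM and the immunoproteasome gene Psmb8 from 65.6 to 200.6 CPM. Of 8 annexins 6 rose, with Anxa2 at 90.8 and 681 CPM (list adjusted p = 1.2e-07, adjusted p = 0.0401 with an estimated correlation). Of 9 S100 genes 7 rose, with S100a6 at 188 and 525 CPM (adjusted p = 5.69e-06, adjusted p = 0.0401 with an estimated correlation), and the 7 include S100a8 and S100a9, which are also neutrophil markers. Of 6 galectin genes 3 rose and 1 fell, with Lgals1 at 337 and 1425 CPM (adjusted p = 6.91e-05, adjusted p = 0.0401 with an estimated correlation). Of 13 cathepsin genes 9 rose and 1 fell, with Ctsw at 92.8 and 287 CPM (adjusted p = 5.69e-06, adjusted p = 0.0401 with an estimated correlation), and the 9 include Ctss, which is also a macrophage marker.

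Other families included condensin and cohesin, of whose 13 genes 7 rose and 2 fell (adjusted p = 8.82e-05, adjusted p = 0.0401 with an estimated correlation). Of 300 genes named Zfp, mostly zinc finger proteins, 72 fell and 5 rose (median -0.53, adjusted p = 2.37e-06, adjusted p = 0.0465 with an estimated correlation), while fewer genes were detected in papain libraries (17974 against 21117 on average). The 72 include Zfp36, which is also in the immediate early list. Of 13 Kruppel-like factor genes 8 fell and 1 rose (median -0.92, adjusted p = 0.000197, adjusted p = 0.143 with an estimated correlation), with Klf10 at 321 CPM in PBS and 111 CPM in papain libraries, and the 8 include Klf4 and Klf6, which are also in the immediate early list weighed below. Of 9 Arp2/3 complex genes 8 rose (median 0.47, adjusted p = 0.000759, adjusted p = 0.166 with an estimated correlation), and of 77 mitochondrial ribosomal protein genes 32 rose and 2 fell (median 0.51, adjusted p = 0.000312, adjusted p = 0.166 with an estimated correlation). Of 9 chaperonin genes 7 rose (adjusted p = 0.000253, adjusted p = 0.166 with an estimated correlation), of 17 vacuolar ATPase genes 10 rose (adjusted p = 0.00518, adjusted p = 0.121 with an estimated correlation), and of 25 kinesin genes 9 rose, among them Kif11 and Kif20a of the cell cycle list, and 2 fell (adjusted p = 0.00658, adjusted p = 0.0982 with an estimated correlation). Of 14 serpin genes 7 rose and 1 fell (adjusted p = 0.00981, adjusted p = 0.218 with an estimated correlation), and of 11 tubulin genes 6 rose and 1 fell (adjusted p = 0.0218, adjusted p = 0.166 with an estimated correlation). Of 8 Gimap genes 4 fell and 1 rose (median -0.38, adjusted p = 0.0107, adjusted p = 0.283 with an estimated correlation), and of 9 genes of NF-kappaB inhibitors and A20 partners 4 fell, among them Nfkbia of the immediate early list, and 3 rose (median -0.33, adjusted p = 0.0107, adjusted p = 0.166 with an estimated correlation). The other 3 families did not pass, namely histones with 3 genes higher and 9 lower of 24 (median -0.72, adjusted p = 0.0888, adjusted p = 0.398 with an estimated correlation), MHC class I genes with 6 higher and 1 lower of 14 (median 0.24, adjusted p = 0.116, adjusted p = 0.507 with an estimated correlation) and dual specificity phosphatases with 2 higher and 3 lower of 18 (median 0.08, adjusted p = 0.492, adjusted p = 0.507 with an estimated correlation).

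Immediate early genes fell after papain, with a list median of -1.10. A few abundant genes taking more of the papain counts would lower all others, but the 10 most abundant genes outside the list shifted the other genes by only 0.00369 on the log2 scale (-0.0026 to 0.0141 over pairs of libraries), which argues against that as the cause. Stronger dissociation or handling stress in the PBS libraries may raise both kinds of stress gene there, so that both look lower after papain. Yet the 6 heat shock chaperones had a median of -0.258 (range -0.579 to 0.27, 1 lower), while 21 of the 25 other genes were lower (median -1.253). This does not decide, because dissociation need not induce chaperones as strongly as immediate early genes, and the libraries' handling is not recorded. An effect of papain on the cells before sorting stays open and was not tested.

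Of 16 macrophage markers 7 rose after papain, Chil3 among them (list adjusted p = 0.00692, adjusted p = 0.949 with an estimated correlation), as did Retnla except with voom (0.257, in a range of 2.8e-19 to 0.257). A candidate explanation is macrophages among the sorted cells, and sorting of ILC2s would normally remove them. The gain of Lyz2, an abundant macrophage gene, was 0.398 of the gain of Chil3 (168 against 423 CPM), and that of Ctss was 0.188. The ratios of Csf1r (0.013), C1qb (0.018), Marco (0.007) and Mrc1 (0.008) were small. A gain in CPM depends on a gene's level as well as its fold, so small ratios do not show that these genes failed to rise. The median log2 fold change of the list was 2.02, and 11 of its 16 markers rose and 0 fell at an unadjusted edgeR p under 0.05. The level of Lyz2 overlapped between treatments, and its gain rested largely on papain replicate 3. The value therefore does not decide, and the macrophages of a papain-treated lung may have another makeup. Expression of Chil3 in ILC2s stays open and was not tested.

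Respiratory chain genes are short, with a median of 646 bp against 2321 bp for the 11760 tested genes with a length, and short genes tended to higher folds. With the trend on length removed the list median went from 0.79 to 0.440 (interquartile range 0.185 to 0.644 over its genes), which argues against length as the whole cause. Ribosomal protein genes, with a median of 595 bp, had a median log2 fold change of 0.05. With the trend on GC content removed the median was 0.723 (interquartile range 0.498 to 0.884), which argues against GC content as the cause. Part of the rise may follow length, and the treatment stays open as a cause, untested. No other planned list had the trend on length removed.

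Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 4392 called genes, and the highest of the others gave 0 by edgeR's test, where the most genes at an unadjusted p under 0.05 were 485 and the most by DESeq2 were 49. The 10 splits are too few for a share under 0.05. Every other split put libraries of both treatments in each group, so the difference between treatments counted there as spread within groups. Few calls were therefore bound to arise, and the contrast does not tell treatment from anything else that separates the PBS from the papain libraries.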
